A study of Mus musculus with 9 samples.

How the data were processed

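Gene expression was measured in keratinocytes of the mouse tongue on 9 Affymetrix mouse genome arrays with 45101 probe sets each. Per the labels' protocols, epithelial cells of the oral mucosa of BALB/c mice were suspended at 10000000 cells per ml, and C57BL/6J mice received 50 µl of this suspension under the skin of the neck. After 7 days the same mice received 25 µl into the tongue submucosa, and groups of 6 mice were killed 48 h or 96 h later beside a control group that was left unmanipulated. Tongue epithelium was freed with dispase overnight and dispersed with trypsin, RNA was extracted with Trizol, and biotin-labelled cRNA was hybridised, per the labels' protocols. There were 3 groups of 3 arrays: control (replicates 4, 5 and 6), 48h (replicates 1, 2 and 3) and 96h (replicates 1, 2 and 3). The labels do not say how the 6 mice of a group were divided over the 3 arrays. The p-values below therefore measure only the spread between these arrays. The sample labels give the strain as BALB/c where the protocol names C57BL/6J hosts, so the strain is left open.

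The deposited values are signal intensities made with MAS5, per the submitters' processing notes. No software version or scaling target was stated. The deposited intensities are linear, from 0.79 to 13980.2 arbitrary units, and were used as deposited. The mean signal of an array with 2% trimmed from each tail lay between 142 and 155. Array data give no counting depth, and the number of arrays limits the precision.

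Of the probe sets, 34958 carried a single gene symbol in the platform annotation, 932 carried several and 9211 named no gene. Of the probe sets with a single symbol, 34754 matched a gene in the RefSeq table by Entrez number, and 0 symbols changed. No genome build was stated, so no coordinates are given. Each of the 18194 genes with a probe set was represented by the probe set with the highest mean over all arrays. The 40% of genes with the lowest mean were left out, which left 10916 genes with a mean signal of at least 67.3.

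Signals were transformed as log2 of the signal plus 16, with no further normalization, and fold changes are ratios of signals with this 16 added. All 9 arrays entered a single linear model in limma 3.58.1 under R 4.3.3 (package data.table, version 1.17.8, for file handling), with moderated statistics and a mean-variance trend (6 residual and 4.54 prior degrees of freedom). The 3 comparisons were 48h against control, 96h against control and 96h against 48h, and a moderated F test covered all 3 groups. Adjusted p-values are Benjamini-Hochberg values over the genes tested, two-sided, with a threshold of 0.05. Genes said to rise, fall or change passed this threshold. Errors of log2 changes are standard errors (SE) of the model, and errors of signals are standard deviations (SD, n = 3 arrays).

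The gene lists, 36 in number, were written before the data were examined. They covered keratinocyte layers, junctions, interferon and antigen presentation genes, chemokines, cytokines, stress responses, metabolism, cell cycle, cell death, ribosomal proteins, strain markers and markers of other cell types. Of their 807 entries, 79 matched no probe set with a single gene. The 30 lists with at least 5 tested genes were tested with limma's camera at its preset correlation of 0.01, with adjustment over the 30 lists. The same test with an estimated correlation stands beside each call, and the test fry is given where its call differed. For each called list, and for some of the others, the number of genes that passed is given over all genes tested and adjusted over the list alone.

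The genes named in the text followed a rule also fixed before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among called genes whose groups of arrays did not overlap. From each list it took up to 4 called members with the largest change, or 2 members with the highest signal where none passed. Clone names and predicted genes were counted and not named. The strain checks Nnt, H2-Ea and Gbp2b were named whatever their values. Other genes named from a list are given to describe that list.

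The model was tested on simulated data for the 10916 genes with 200 genes changed and a further 20 shifted as a list. For 48h against control it recovered 77.6% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 13 of 10696 unchanged genes called. For 96h against control it recovered 74.6% and 100%, with 11 false calls, and for 96h against 48h 73.1% and 98.5%, with 10 false calls. A simulated list of 20 genes shifted by 0.5 gave camera p-values of 5.2e-30, 2.9e-37 and 5.8e-31, and an unshifted list gave 0.867, 0.403 and 0.354. The simulated genes varied independently of each other. The simulation therefore did not test the preset correlation of 0.01 on lists whose members move together, such as the type I interferon-stimulated genes (estimated correlation 0.48). It also gave each gene the same spread in every group, as the model assumes. In the data the SD of log2 differences between 2 arrays of a group was 0.145 to 0.199 in control, 0.241 to 0.278 at 48h and 0.175 to 0.269 at 96h. The recovered shares hold only for equal spread.

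RNA handling was described by the log2 ratio of the 3' to the 5' control probe sets of Gapdh and beta-actin, and by the bacterial control RNAs added before labelling and before hybridisation. These measures were compared between groups by two-sided exact permutation tests, for which 3 arrays against 3 cannot give a p under 0.1. Alternatives covered quantile normalization, centring each array on its median, pseudocounts of 1 and 64, no filter and a filter at 60%, other choices of probe set, other variance models, array weights, only the 2 groups compared, a block for the replicate number, and leaving out each array in turn. A covariate for the 5' to 3' ratio of the bacterial control RNAs, gene-by-gene array weights, a list of hair-type keratin genes and a test of probe sets without a single gene name were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.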

Results

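Transcript levels were measured in tongue keratinocytes of 3 control arrays, 3 arrays taken 48 h and 3 taken 96 h after the tongue injection of BALB/c oral epithelial cells into mice that had received the same kind of cells 7 days earlier. The submitters describe the time points as stages of an oral adaptive immune response. The arrays parted by group. The first principal component of the tested genes held 49.5% of the variance and put the 48h arrays (scores 13.1 to 29.0) opposite the 96h arrays (-22.0 to -12.8). The second component held 24.0% and put the control arrays (7.47 and above) opposite the rest (-0.654 and below). Between any of the 3 groups, 3140 of 10916 tested genes differed by the moderated F test.

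The control RNAs gave a measure of sample handling. The bacterial poly-A RNAs, which are added to the RNA before labelling, had a mean log2 level of 9.43 ± 0.07 (SD, n = 3) in control, 9.41 ± 0.06 at 48h and 8.64 ± 0.10 at 96h. Their level at 96h was 1.72-fold lower than in control, with an exact permutation p of 0.1, the smallest that 3 arrays against 3 allow, and 0.375 after Benjamini-Hochberg adjustment over 15 comparisons. Their log2 ratio of 5' to 3' signal was -1.23 ± 0.03 in control, -1.07 ± 0.25 at 48h and -1.70 ± 0.62 at 96h, with the lowest value, -2.41, on 96h replicate 3. The 3' to 5' log2 ratio of beta-actin was 1.38 ± 0.11 in control, 0.78 ± 0.34 at 48h and 1.42 ± 0.66 at 96h. At 48h it was 1.51-fold lower than in control, with the same exact permutation p of 0.1 (0.375 adjusted). That of Gapdh was 0.30 ± 0.10, 0.08 ± 0.21 and 0.20 ± 0.34.

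**Figure D1:**
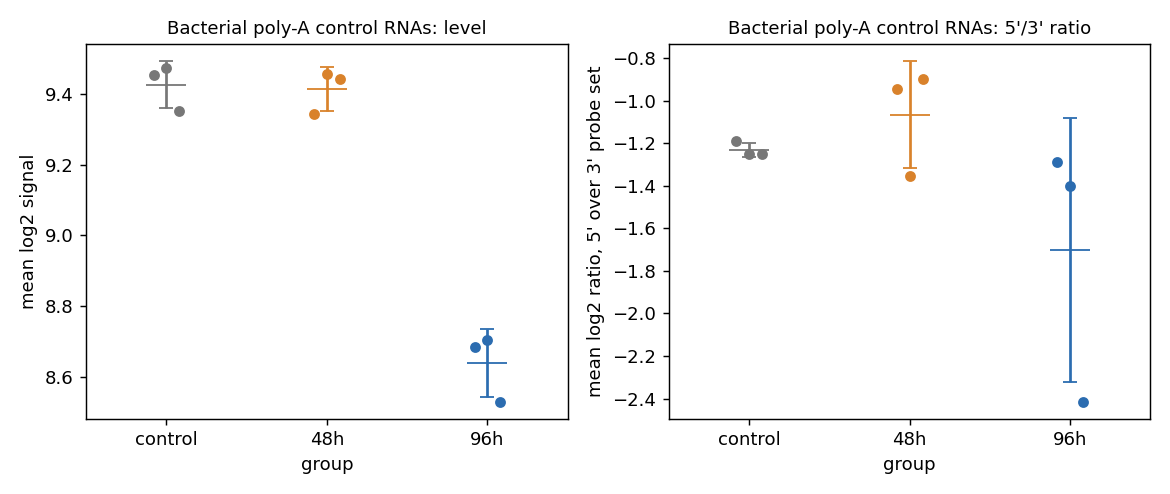
Bacterial poly-A control RNAs on each array. Left, mean log2 signal of their 3' probe sets; right, mean log2 ratio of 5' to 3' signal; dots are arrays, horizontal marks group means and bars SD (n = 3). The 96h arrays had a mean level of 8.64 against 9.43 in control.

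On the 48h arrays immediate early genes, which cells switch on soon after a stimulus, were higher than in control. So were chemokines, genes of NF-kappaB feedback and chaperones of the endoplasmic reticulum, while cell cycle genes were lower. With an estimated correlation 1 of 30 lists passed camera, the chemokines, and fry called 17. For the immediate early genes, stress during cell isolation and a response in the animal cannot be told apart, as set out further below. Fosl1, a subunit of the AP-1 transcription factor, rose 8.07-fold, from a signal of 67.2 ± 10.4 (SD, n = 3) in control to 664 ± 147 (log2 change 3.01 ± 0.17, adjusted p = 4.7e-06). Ptgs2, the inducible enzyme of prostaglandin synthesis, rose 7.55-fold (2.92 ± 0.24), Tnfaip3, a feedback inhibitor of NF-kappaB, 7.24-fold (2.86 ± 0.13), and Cxcl1, a chemokine that draws neutrophils, 7.01-fold (2.81 ± 0.15). The other largest rises were those of the vasoactive peptide genes Adm (2.82) and Edn2 (2.79), the transcription factors Egr3 (2.74) and Egr2 (2.64), the tight junction gene Cldn4 (2.74) and Pdk4 (2.62), a kinase that restrains pyruvate oxidation. For Egr3, 1 of its 2 probe sets had this sign. The largest falls were those of the hair-type keratin genes Krtap13 (-1.79 ± 0.29), Krt34 (-1.22) and Krtap13-1 (-1.16), and of the non-coding RNA gene Rab26os (-1.27) and the planar polarity gene Prickle2 (-1.13). Next to them stood the cell division genes Ncapg2 (-1.22), Kntc1 (-1.18), Ccne2 (-1.17), Plk4 (-1.16) and Rrm2 (-1.15). For each of these genes all 3 arrays at 48h lay on the same side of all 3 control arrays.

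Of 26 tested immediate early and heat shock genes, 19 rose and 0 fell at 48h (21 and 0 adjusted over the list alone). Their mean log2 change was 1.12 ± 0.18 (SD over arrays, n = 3) and the list passed camera (adjusted p = 5.3e-19, but adjusted p = 0.097 with an estimated correlation). Examples are Fosb (2.53 ± 0.17), Dusp5 (2.29 ± 0.22), a phosphatase that restrains ERK, and Zfp36 (2.25 ± 0.17), which shortens the life of cytokine mRNAs. On the same arrays the 3' to 5' ratio of beta-actin was 1.51-fold lower than in control, as given above for all groups. Of 20 endoplasmic reticulum stress genes, 10 rose (11 adjusted over the list alone) with a mean of 0.47 (adjusted p = 6.6e-07, and adjusted p = 0.068 with an estimated correlation). Among them were the chaperone gene Hspa5 (1.27 ± 0.13) and Ddit3 (1.14 ± 0.10), a transcription factor of prolonged stress. Of 18 chemokines, 7 rose (7 adjusted over the list alone), with a mean of 0.63 and adjusted p = 3.0e-06. This list alone also passed with an estimated correlation (adjusted p = 0.046). Besides Cxcl1 they included Cxcl10 (2.02 ± 0.35), which draws activated T cells, Cxcl2 (1.89 ± 0.16) and Ccl20 (1.26 ± 0.11), which draws Langerhans cell precursors and Th17 cells. Of 15 genes of pattern recognition and NF-kappaB feedback, 7 rose (7 adjusted over the list alone), with a mean of 0.63 (adjusted p = 1.0e-05, and adjusted p = 0.097 with an estimated correlation). Among them were Nfkbiz (2.22) and the inhibitor gene Nfkbia (1.23).

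Lists of antigen presentation and interferon response genes were also called upwards at 48h at the preset correlation, although at most 5 members of each passed over all genes. Of 16 MHC class I presentation genes, 5 rose (12 adjusted over the list alone), with a mean of 0.60 (adjusted p = 3.8e-06, and adjusted p = 0.21 with an estimated correlation). B2m, the light chain of class I molecules, rose 3.11-fold (1.64 ± 0.28), and the heavy chain genes H2-K1 and H2-D1 rose by 1.46 ± 0.19 and 1.24 ± 0.17. Of 18 type I interferon-stimulated genes, 5 rose (10 adjusted over the list alone), with a mean of 0.62 ± 0.35 (SD over arrays) and adjusted p = 1.6e-05. Of 11 interferon-gamma response genes, 2 rose (2 adjusted over the list alone), Irf1 (1.90 ± 0.16) and Cxcl10, with a mean of 0.81 ± 0.51 (SD over arrays) and adjusted p = 0.00090. Both had an adjusted p = 0.35 with an estimated correlation. For the type I list, 48h replicate 1 lay at 0.24 above the control mean, and so did control replicate 6. Of 9 MHC class II genes, 2 rose (2 adjusted over the list alone; adjusted p = 0.0083, and adjusted p = 0.35 with an estimated correlation). Of 8 cytokine genes, 1 rose (4 adjusted over the list alone), Tnf (0.64 ± 0.11), with adjusted p = 0.021 for the list, adjusted p = 0.35 with an estimated correlation, and no call without 48h replicate 3 (0.13; over all alternatives 0.00063 to 0.13). Of 13 co-stimulation and adhesion genes, 3 rose (3 adjusted over the list alone), among them the leukocyte adhesion gene Icam1 (1.29 ± 0.10), with adjusted p = 0.015, and adjusted p = 0.17 with an estimated correlation.

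Cell cycle genes fell at 48h. Of 27, 16 were lower and 0 higher (18 and 0 adjusted over the list alone), with a mean of -0.51 ± 0.18 (SD over arrays), adjusted p = 1.5e-09, and adjusted p = 0.21 with an estimated correlation. Ribonucleotide reductase gene Rrm2 was 2.22-fold lower, and the mitotic genes Bub1 (-0.97 ± 0.16), Ccna2 (-0.96 ± 0.15) and Top2a (-0.90 ± 0.15) were lower as well. Of 27 differentiation genes, 4 rose (4 adjusted over the list alone), among them Lypd3 (0.72 ± 0.15) and the transglutaminase gene Tgm1 (0.49 ± 0.12). The list passed (adjusted p = 0.012), but not with an estimated correlation (adjusted p = 0.51), nor without control replicate 5 (0.072) or without 48h replicate 3 (0.073; over all alternatives 0.00015 to 0.073). Glycolysis and hypoxia genes passed with 5 of 20 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.0068, and adjusted p = 0.21 with an estimated correlation). Among them was the glucose transporter gene Slc2a1 (0.73 ± 0.09). Of 21 cell death genes, 6 rose and 2 fell (6 and 3 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.21 with an estimated correlation), and the call ended with the lowest 60% of genes left out (0.15; over all alternatives 0.0025 to 0.15). Their largest rises were those of Pmaip1 (1.84 ± 0.17), which promotes apoptosis, and Mcl1 (1.16 ± 0.10), which restrains it. Wound healing and matrix remodelling genes did not pass (adjusted p = 0.26; mean 0.37, median -0.06). Of 14, 5 rose (5 adjusted over the list alone), led by the growth factor gene Hbegf (2.54 ± 0.25), and the list passed with the mean of a gene's probe sets (0.00085) and with fry (0.00093).

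Markers of other cell types did not pass as lists at 48h: T and NK cells (adjusted p = 0.26), Langerhans and dendritic cells (0.37), macrophages and monocytes (0.41), neutrophils (0.37), fibroblasts (0.70), skeletal muscle (0.10), nerve, Schwann and pigment cells (0.17) and taste and minor salivary gland cells (0.65). Neither did the basal layer (0.26), wound and stress keratins (0.057), antimicrobial proteins (0.65), tight junction and desmosome (0.65), oxidative phosphorylation (0.40), lipid and cholesterol synthesis (0.70) or ribosomal proteins (0.97). The wound and stress keratins passed in 10 of 22 alternatives, among them quantile normalization (0.041), centring (0.029), no filter (0.046) and leaving out control replicate 6 (0.024), 48h replicate 1 (0.016), 96h replicate 1 (0.047) or 96h replicate 3 (0.041; over all alternatives 0.016 to 0.24). Oxidative phosphorylation genes passed downwards after quantile normalization (mean -0.19, 0.041; over all alternatives 0.041 to 0.71). Of these lists, members that passed on their own included Pmp22 (1.27 ± 0.17), a myelin gene that other cells also express, and Sprr2h (1.13 ± 0.24). With no filter on low signals the T and NK cell list passed (mean 0.18, adjusted p = 0.0031; over all alternatives 0.0031 to 0.51). Fry called T and NK cells (0.020), skeletal muscle (0.038) and nerve, Schwann and pigment cells (0.048) higher, and for these 3 lists the 48h arrays lay above those of control. Of the 9 T and NK cell genes, however, the only member that passed over all genes, Gzma, fell (-0.34; 0 higher and 1 lower, and the same adjusted over the list alone). Skeletal muscle genes also passed camera without probe sets that can match several transcripts (0.039; over all alternatives 0.039 to 0.28). Fry did not call the differentiation list (0.21). Too few genes of 6 lists were tested for a list test at any time, and at 48h none of their members passed over all genes by limma, while 2 mast cell genes did adjusted over that list alone. Examples at 48h are the complement genes Clu (0.39 ± 0.15) and Cd59a (0.02 ± 0.07) and the B cell genes Ighm (0.19 ± 0.08) and Cd22 (-0.01 ± 0.08). Others are the mast cell genes Hdc (0.23 ± 0.09) and Mcpt4 (0.21 ± 0.08), the endothelial genes Eng (0.23 ± 0.09) and Egfl7 (-0.01 ± 0.09), and the haemoglobin gene Hba-a2 (0.28 ± 0.17).

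In all, 1519 of 10916 genes changed at 48h against control (limma), of which 708 rose and 811 fell. Of these, 176 changed by at least 2-fold, 152 of them upwards. The groups of arrays did not overlap for 34.6% of genes, where chance gives 10%. The count was 578 without control replicate 4, 578 without control replicate 5, 977 without 48h replicate 1 and 850 without 48h replicate 3. The share of called genes that were higher was 46.6%. It was 32.8% after quantile normalization, 30.9% after centring each array on its median and 58.2% with the mean of a gene's probe sets. No excess of falls or rises can therefore be stated for all called genes together. Among the 176 genes changed by at least 2-fold rises prevailed, but that count was not repeated under these alternatives.

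**Figure D2:**
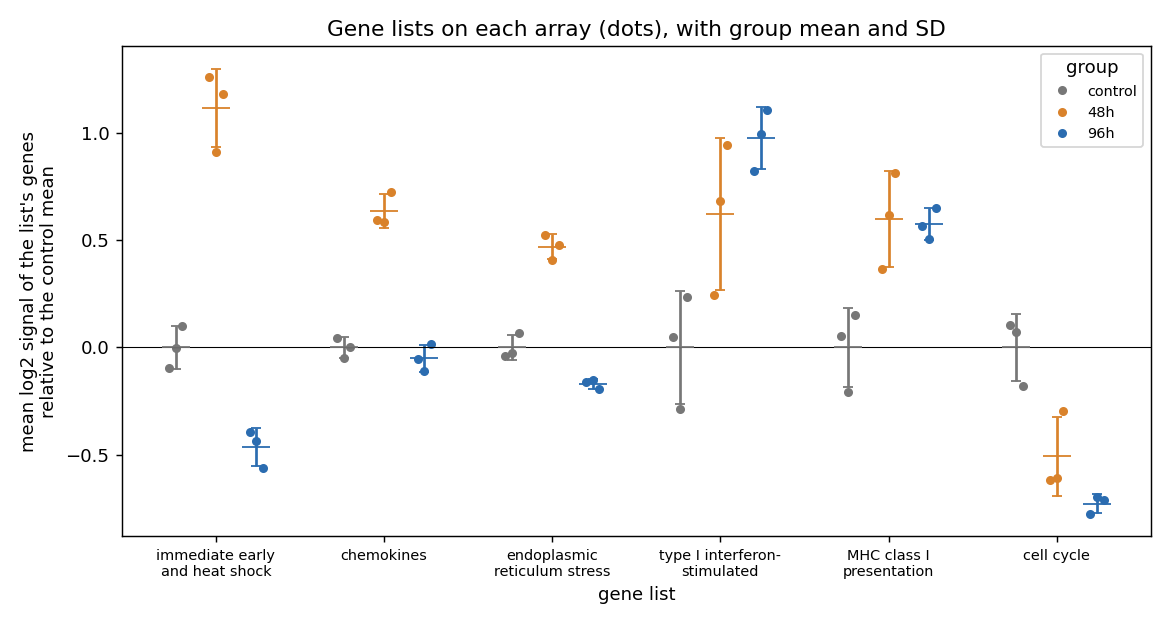
Mean log2 signal of the tested genes of 6 gene lists on each array, relative to the control mean. Dots are arrays, horizontal marks group means and bars SD (n = 3). Immediate early and heat shock genes were at 1.12 at 48h and -0.46 at 96h, type I interferon-stimulated genes at 0.62 and 0.97, and cell cycle genes at -0.51 and -0.73.

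At 96 h interferon-stimulated and antigen presentation genes were higher than in control, cell cycle genes were lower, and immediate early genes were below their control level. These were list calls at the preset correlation. With an estimated correlation 0 of 30 lists passed camera (4 at an unadjusted p under 0.05), and fry called 6. Ifit1, an antiviral gene induced by interferon, rose 4.32-fold, from a signal of 86.3 ± 34.7 (SD, n = 3) to 415 ± 101 (log2 change 2.11 ± 0.35, adjusted p = 0.0047). Other interferon-induced genes among the largest rises were Ifi27l2b (1.91 ± 0.39), Oasl2 (1.86 ± 0.34), Ifi47 (1.83 ± 0.51), Gbp3 (1.81 ± 0.39), Rtp4 (1.75 ± 0.35), Usp18 (1.68 ± 0.24) and Xaf1 (1.62 ± 0.30). For Xaf1, 1 of its 2 probe sets had this sign. The cornified envelope gene Sprr2i (1.85 ± 0.43) and B2m (1.71 ± 0.28) completed the 10 largest. The largest falls were those of the stress and growth response genes Atf3 (-2.01 ± 0.16), Egr2 (-1.76), Klf2 (-1.72) and Ccn2 (-1.65), the chemokine gene Cxcl1 (-1.66) and the circadian clock gene Per2 (-1.55). To these came Wfdc17 (-1.70), Wfdc18 (-1.65), Ltf (-1.61) and Dmbt1 (-1.57), which encode secreted proteins of mucosal defence. For each of these genes the 3 arrays at 96h did not overlap those of control.

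Of 18 type I interferon-stimulated genes, 13 rose and 0 fell at 96h (13 and 0 adjusted over the list alone), with a mean of 0.97 ± 0.14 (SD over arrays, n = 3), adjusted p = 8.1e-11, and adjusted p = 0.34 with an estimated correlation. Of 11 interferon-gamma response genes, 7 rose (8 adjusted over the list alone), among them the GTPase genes Igtp (1.49 ± 0.38) and Gbp2 (1.48 ± 0.33). Their mean was 1.05 ± 0.47 (SD over arrays; adjusted p = 2.0e-05, and adjusted p = 0.34 with an estimated correlation). Of 16 MHC class I genes, 8 rose (8 adjusted over the list alone), with a mean of 0.57 (adjusted p = 4.2e-08, and adjusted p = 0.34 with an estimated correlation). Besides B2m these were among others the transactivator gene Nlrc5 (1.16 ± 0.29), the immunoproteasome gene Psmb8 (1.14 ± 0.28) and H2-K1 (1.11 ± 0.19). Of 9 MHC class II genes, 3 rose (6 adjusted over the list alone), among them the invariant chain gene Cd74 (0.61 ± 0.16), with adjusted p = 0.015, adjusted p = 0.46 with an estimated correlation, and no call with array weights (0.095; over all alternatives 0.0049 to 0.095). Of 8 cytokine genes, 1 rose (3 adjusted over the list alone), Il1f6 (1.46 ± 0.33), which encodes interleukin-36 alpha (list adjusted p = 0.013, and adjusted p = 0.34 with an estimated correlation; 0.057 with no filter; over all alternatives 0.0024 to 0.057). Of 13 co-stimulation genes, 1 rose (1 adjusted over the list alone), Lgals9 (1.32 ± 0.21), and the list did not pass (adjusted p = 0.35).

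Cell cycle genes fell at 96h, with 20 of 27 down and 0 up (23 and 0 adjusted over the list alone), a mean of -0.73 ± 0.04 (SD over arrays), adjusted p = 1.2e-13, and adjusted p = 0.34 with an estimated correlation. Mcm5, part of the replicative helicase, was 2.34-fold lower (-1.23 ± 0.11), Ccna2 2.29-fold lower (-1.19 ± 0.15), and Tk1 fell by 1.15 on the log2 scale. The fall from 48h to 96h was not itself called for this list (adjusted p = 0.085), but it was in 7 of 23 alternatives, among them quantile normalization (0.045; over all alternatives 0.019 to 0.46). Of 26 immediate early and heat shock genes, 8 fell and 0 rose (10 and 0 adjusted over the list alone), with a mean of -0.46 ± 0.09 (SD over arrays), adjusted p = 4.2e-05, and adjusted p = 0.44 with an estimated correlation. Besides Atf3 and Egr2 they included Fosb (-1.24 ± 0.17) and Hspa1a (-1.01 ± 0.13). On the same arrays the level of the bacterial poly-A RNAs was 1.72-fold lower than in control, as given above for all groups.

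Differentiation genes were higher as a list at 96h, with 3 of 27 passing (3 adjusted over the list alone), a mean of 0.39, adjusted p = 6.5e-07, and adjusted p = 0.34 with an estimated correlation. They were Krt76 (1.03 ± 0.26), a keratin of the oral suprabasal layers, the cornified envelope gene Rptn (1.00 ± 0.26) and Lypd3 (0.54 ± 0.15). Of 12 wound and stress keratin genes, 2 rose (4 adjusted over the list alone), Il1f6 and Krt16 (0.90 ± 0.21), with adjusted p = 0.00018, and adjusted p = 0.34 with an estimated correlation. Of 21 lipid and cholesterol synthesis genes, 5 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00016, and adjusted p = 0.34 with an estimated correlation). The largest rises were those of the fatty acid elongase gene Elovl4 (1.11 ± 0.15) and Insig1 (0.93 ± 0.17), a regulator of sterol synthesis. Tight junction and desmosome genes did not pass (0.095), except in 3 of 22 alternatives, such as without control replicate 6 (0.035) or without 96h replicate 3 (0.025; over all alternatives 0.025 to 0.40). Basal layer genes did not pass either (adjusted p = 0.17), with 1 of 15 higher and 2 lower (1 and 2 adjusted over the list alone). They passed in 3 of 22 alternatives, such as without 96h replicate 1 (0.025; over all alternatives 0.025 to 0.48).

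Macrophage and monocyte markers passed at 96h (adjusted p = 0.045, and adjusted p = 0.46 with an estimated correlation), with 3 of 9 higher and 1 lower (3 and 1 adjusted over the list alone). The pan-leukocyte gene Ptprc (0.79 ± 0.22) and the cathepsin gene Ctss (0.75 ± 0.17) rose, and Cd14 (-0.37 ± 0.09) fell. Laptm5 rose by 0.61 ± 0.16 but was at -0.11 when probe sets that can match several transcripts were left out. This call ended in 10 of 21 alternatives, among them quantile normalization (0.057) and centring (0.068), where the mean was 0.30 and 0.26 against 0.24, leaving out those probe sets (mean 0.16, 0.26), array weights (mean 0.18, 0.15), and leaving out control replicate 6 (0.11), 96h replicate 3 (0.10), 48h replicate 2 (0.051) or 48h replicate 3 (0.062). Over all alternatives it ranged from 9.4e-06 to 0.26. T and NK cell markers did not pass (adjusted p = 0.14; 0 of 9 called by limma), but passed with no filter on low signals (mean 0.30, adjusted p = 2.2e-06; over all alternatives 2.2e-06 to 0.27). They also passed camera with the mean of a gene's probe sets (mean 0.17, adjusted p = 0.013). The antimicrobial list did not pass (0.35), with Slpi (1.26 ± 0.32) higher and Ltf and Wfdc18 lower (1 higher and 2 lower; 4 and 2 adjusted over the list alone). Of 6 taste and minor salivary gland genes, 3 fell (3 adjusted over the list alone), Krt8 (-1.14 ± 0.19), Krt18 (-1.07 ± 0.21) and Krt7 (-0.72 ± 0.21), keratins of simple and glandular epithelia. Krt7 did not pass after either scaling alternative. The list did not pass (0.13), except without control replicate 6 (0.032) or without 96h replicate 2 (0.021; over all alternatives 0.021 to 0.42). The lists for Langerhans and dendritic cells (0.50), neutrophils (0.88), fibroblasts (0.85), skeletal muscle (0.85) and nerve, Schwann and pigment cells (0.70) did not pass. Neither did chemokines (0.96), NF-kappaB feedback (0.72), cell death (0.30), wound healing (0.48), oxidative phosphorylation (0.72), glycolysis and hypoxia (0.54), endoplasmic reticulum stress (0.72) or ribosomal proteins (0.35). With no filter on low signals the Langerhans and dendritic cell list passed (0.043; over all alternatives 0.043 to 0.71). Fry called chemokines and wound healing genes lower (0.019 each). It did not call differentiation (0.10), wound and stress keratins (0.058), interferon-gamma response (0.067), MHC class II (0.14), cytokines (0.087), macrophages (0.20) or lipid synthesis (0.058). Of the lists too small to test, the complement gene Clu rose (0.59 ± 0.15), and the strain check Nnt fell, as given below.

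At 96h 1378 genes changed against control (limma), of which 428 rose and 950 fell. Of these, 119 changed by at least 2-fold, 81 of them downwards. The groups of arrays did not overlap for 37.9% of genes, where chance gives 10%. The count was 397 without control replicate 4, 440 without control replicate 5, 631 without 96h replicate 2 and 703 without 96h replicate 3. It was 904 with the 5' to 3' ratio of the bacterial control RNAs as a covariate, a term chosen after the data were seen. The share of called genes that were higher was 31.1%, 46.8% after quantile normalization and 39.9% after centring.

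From 48 h to 96 h immediate early genes, chemokines and NF-kappaB feedback genes fell, while interferon-induced genes went in both directions. With an estimated correlation 0 of 30 lists passed camera in this comparison (5 at an unadjusted p under 0.05), and fry called 10. Among the largest falls were those of Cxcl1 (log2 change -4.47 ± 0.15, adjusted p = 1.7e-07), Egr2 (-4.39 ± 0.19), Ptgs2 (-4.09 ± 0.24), Atf3 (-4.01 ± 0.16) and Fosl1 (-3.63 ± 0.17). The size of these falls depended on the value added to each signal, because signals at 96h were low (21.1 ± 1.66 for Egr2, 35.7 ± 11.4 for Ptgs2, 38.3 ± 7.91 for Fosl1; SD, n = 3). With 1 added in place of 16 Egr2 was at -5.12, Ptgs2 at -4.59 and Fosl1 at -4.07, and with 64 added they were at -3.28, -3.21 and -2.81. Adm (-4.26), Egr4 (-3.77), Fosb (-3.77), the metalloproteinase gene Adamts1 (-3.61) and the transcription factor gene Klf2 (-3.47) made up the 10 largest falls. The largest rises were those of Krtap13 (1.66 ± 0.29), Rptn (1.44 ± 0.26), the lysozyme-like gene Lyg1 (1.34 ± 0.39), Ifit1 (1.33 ± 0.35), Gbp3 (1.31 ± 0.39) and Ttll7 (1.28 ± 0.09). Prickle2 (1.25), Bpifa5 (1.24), Krtap13-1 (1.21) and Sh3kbp1 (1.20) completed the 10. The arrays of both times did not overlap for any of these genes.

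Of 26 immediate early and heat shock genes, 23 fell and 0 rose (23 and 0 adjusted over the list alone), with a mean of -1.58, adjusted p = 1.3e-18, and adjusted p = 0.19 with an estimated correlation. Of 18 chemokines, 9 fell (11 adjusted over the list alone; mean -0.68, adjusted p = 0.00086, and adjusted p = 0.14 with an estimated correlation), among them Cxcl2 (-2.00) and Ccl20 (-1.43). Of 20 endoplasmic reticulum stress genes, 11 fell (12 adjusted over the list alone; mean -0.64, adjusted p = 0.00089, and adjusted p = 0.19 with an estimated correlation), among them Hspa5 (-1.68). Of 15 NF-kappaB feedback genes, 8 fell and 1 rose (9 and 2 adjusted over the list alone; mean -0.67, adjusted p = 0.0018, and adjusted p = 0.22 with an estimated correlation), with Tnfaip3 (-3.37) and Nfkbiz (-3.19) the largest. Lipid synthesis genes rose, 6 against 2 that fell of 21 (8 and 2 adjusted over the list alone; mean 0.18, adjusted p = 0.0054, and adjusted p = 0.59 with an estimated correlation). Type I interferon-stimulated genes passed with 2 higher and 1 lower (2 and 1 adjusted over the list alone; mean 0.35, adjusted p = 0.036, and adjusted p = 0.78 with an estimated correlation), but not after quantile normalization (0.077) or centring (0.085; over all alternatives 0.0011 to 0.13), where the mean was larger (0.45 and 0.43). Interferon-gamma response genes did not pass, with 3 of 11 higher and 2 lower (3 and 3 adjusted over the list alone; mean 0.23, adjusted p = 0.33). Gbp3 and Gbp2 (1.03) rose, and Irf1 (-2.18) and Cxcl10 (-1.60) fell. The list's mean was -0.11 with the covariate for the control RNAs and -0.03 without 48h replicate 1, and reached 0.48 in another leave-out. MHC class I genes did not pass, with 0 of 16 called by limma (0 adjusted over the list alone; adjusted p = 0.86), and B2m was at 0.07 ± 0.28. Fry called neither the lipid list (0.065) nor the type I interferon list (0.45), and it called co-stimulation (0.00065), cell death (0.0016), glycolysis and hypoxia (0.0010) and skeletal muscle genes (0.0073) lower. Wound healing genes passed narrowly (5 of 14 lower, 7 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.22 with an estimated correlation). So did basal layer genes (4 of 15 lower and 1 higher, 6 and 1 adjusted over the list alone; adjusted p = 0.049, and adjusted p = 0.59 with an estimated correlation). The calls ended in 7 and 11 of 23 alternatives, among them leaving out control replicate 5 (0.053 and 0.057), with ranges of 0.0044 to 0.17 and 0.0073 to 0.14.

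Markers of other cell types went in both directions from 48h to 96h, and those of their lists that could be tested did not pass camera. With no filter on low signals the macrophage and monocyte list passed camera upwards (mean 0.17, adjusted p = 0.013, and 0.013 to 0.65 over all alternatives). Gzma of T and NK cells (0.37), Ptprc of leukocytes (0.74) and the B cell gene Tnfrsf13c (0.55) rose, while Cd14 of macrophages (-0.42), Ighm of B cells (-0.38) and Pmp22 (-1.61) fell. Ltf fell as well (-1.49). It is on the neutrophil list, but is also named above among the secreted proteins of mucosal defence, so its fall does not speak for neutrophils alone. Of 9 skeletal muscle genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), such as Cox6a2 (-0.65), with the arrays of both times apart, although the list did not pass camera (adjusted p = 0.16). Of 6 taste and minor salivary gland genes 3 fell (3 adjusted over the list alone), Krt8 (-1.26), Krt18 (-1.22) and Krt7 (-1.04). That list did not pass (0.16), except in 3 of 22 alternatives, namely no filter (0.031), without probe sets that can match several transcripts (0.048) and without 96h replicate 2 (0.038; over all alternatives 0.031 to 0.50). Of 3 tested mast cell genes 2 fell (2 adjusted over the list alone), Hdc (-0.37) and Mcpt4 (-0.33).

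Between 48h and 96h 2577 genes changed (limma), 886 upwards and 1691 downwards, and 219 by at least 2-fold, 186 of them downwards. The groups of arrays did not overlap for 38.2% of genes, where chance gives 10%. The count was 1546 without 96h replicate 2, 1465 without 96h replicate 3 and 836 with the ratio of the bacterial control RNAs as a covariate. The share of called genes that were higher was 34.4%, but 63.4% after quantile normalization and 58.4% after centring, so the excess of falls turned with the scaling.

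The changes against control at both times shared 343 genes called in the same direction, of which 74 were higher and 269 lower at both. Independent lists of these sizes would share 98.3, a value that does not allow for the control arrays used by both comparisons. Simulated unchanged groups set against the same controls shared 0.01 on average over 100 simulations. No gene was changed in them, so a count near 0 was fixed in advance and is no baseline for the 343. Another 77 genes rose at 48h and fell at 96h, where independent lists would give 61.6, and 11 did the opposite, where independent lists would give 31.8. Across genes, which are not independent replicates, the changes at both times had a correlation of 0.209. Because both used the same 3 control arrays, simulated unchanged groups gave 0.501. The covariance was 0.0190 against 0.00695 in the simulations. Shared genes included the higher B2m and H2-K1 and the lower Rrm2 and Ccna2. Without control replicate 4 the shared count was 111, without control replicate 5 it was 116 and without 96h replicate 2 it was 205.

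**Figure D3:**
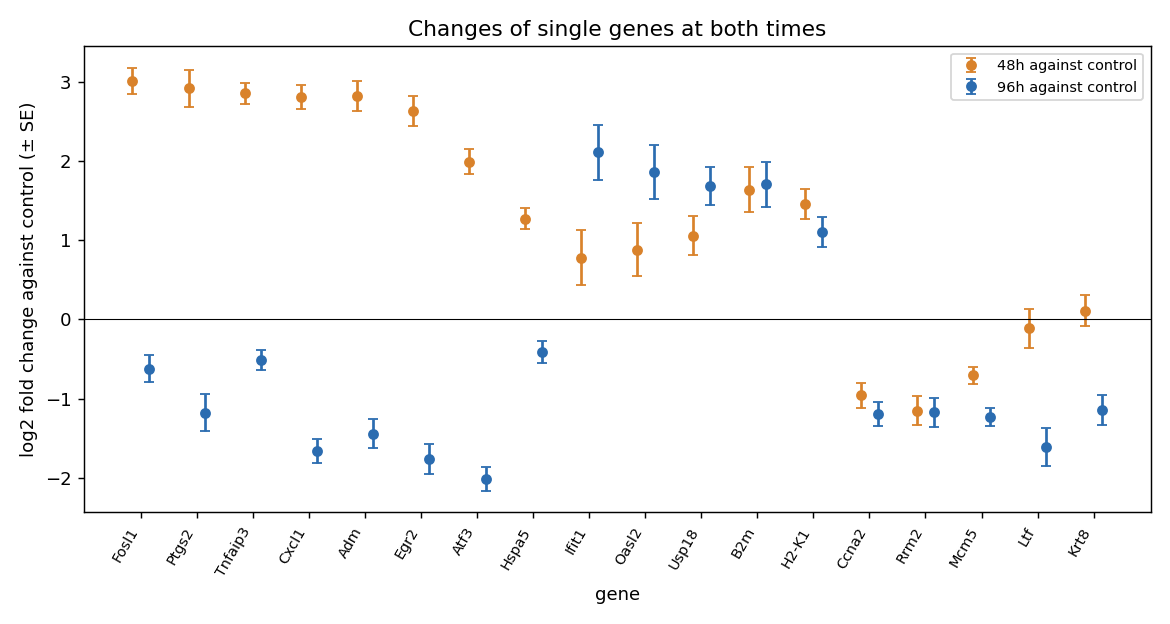
Log2 fold changes against control of 18 genes at 48h and 96h. Dots are estimates of the model and bars are SE. Fosl1 was at 3.01 at 48h, Cxcl1 moved from 2.81 at 48h to -1.66 at 96h, Ifit1 was at 2.11 at 96h, and B2m was at 1.64 and 1.71.

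The genes that mark the strains were measured on every array, since the labels disagree on the strain. Nnt, of which C57BL/6J mice carry a deletion, had mean signals of 136 ± 33.2 (SD, n = 3) in control, 161 ± 23.7 at 48h and 79.0 ± 6.80 at 96h, and was lower at 96h than in control (-0.66 ± 0.15, adjusted p = 0.022). H2-Ea, which is silent in mice of the H2-b haplotype such as C57BL/6J, had mean signals of 236 ± 8.03, 256 ± 31.4 and 208 ± 13.9 and did not change (adjusted p = 0.50 and 0.28 against control). Gbp2b had mean signals of 22.6, 22.8 and 26.1, below the level at which genes were tested. The Nnt signal came from a probe set of the kind that can match several transcripts, so it may not be that of Nnt alone. Where the probes of Nnt lie relative to its deletion is not given, and no array of a known strain was at hand, so these signals do not settle the strain.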

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

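The tests with the bacterial control RNAs as a covariate and of probe sets without a single gene name were chosen after the data had been seen; the differences between both times were part of the plan. The results below are differences between the change at 96h and the change at 48h, each tested by the comparison of 96h with 48h, and signals outside the genes of the report.

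Immediate early and heat shock genes differed between both times by -1.58 (mean log2 change at 96h minus that at 48h), since they were higher than in control at 48h and lower at 96h. With an estimated correlation camera called neither this difference nor the rise at 48h (adjusted p = 0.097 for the rise). With the 5' to 3' ratio of the bacterial control RNAs as a covariate the list kept 96.9% of its mean change at 48h, and without any single array it kept at least 93.7%. The fall at 96h against control, where the control RNAs differed more, moved from -0.46 to -0.37 with the covariate and stayed called (adjusted p = 0.0034; over the alternatives 1.4e-07 to 0.0034), though not with an estimated correlation (adjusted p = 0.44 without the covariate). This argues against a single array as the whole cause, and against cDNA length only as far as these control RNAs measure it. Their ratio differed little between 48h and control (0.16 on the log2 scale, exact permutation p = 0.4). The beta-actin ratio, 1.51-fold lower at 48h, and the level of the control RNAs were not used as covariates, so RNA handling stays open. Stress during cell isolation may have raised such genes, since dispase and trypsin act on living cells. Tissue digestion is known to raise Hspa1a and Hspa1b along with Fos, and here Hspa1a rose at 48h (0.90) while Hspa1b did not pass (0.29, adjusted p = 0.055). Isolation stress and a response in the animal therefore cannot be told apart. The labels' protocols give dispase overnight but no handling time for single arrays, which keeps this open. A response of the tongue epithelium to the injection stays open as well, and no control injected with buffer is in the labels.

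Interferon and MHC class I genes were higher at 96h, and type I interferon-stimulated genes differed between both times by 0.35, a call that ended in 8 of 23 alternatives and with an estimated correlation (adjusted p = 0.78). Without 48h replicate 1 that difference was 0.16 (adjusted p = 0.10; over the alternatives 0.0011 to 0.13). With the covariate this list kept 91.6% of its mean change at 96h, and without any single array it kept at least 85.3%. The interferon-gamma response list moved from 1.05 to 0.79 with the covariate and to 0.80 without 96h replicate 3, its lowest leave-out. MHC class I genes moved from 0.57 to 0.53 with the covariate and to 0.47 without control replicate 5, their lowest. Both lists stayed called at the preset correlation with the covariate and in every leave-out. This argues against a single array as the whole cause, and against cDNA length as far as the 5' to 3' ratio of these control RNAs measures it. Their level, lower at 96h than in control, was not used as a covariate. Leukocytes in the preparation could bring such transcripts. Of 15 tested pan-leukocyte genes 3 rose at 96h, with a median of 0.25. Its upper 95% bootstrap bound, from resampling genes and not arrays, was 0.61, against a median of 1.10 for the 18 interferon-stimulated genes. The bound lay below that median, which had been set beforehand as the outcome against leukocytes. That measure was wrong for genes of such low signal, and leukocytes as a source cannot be told apart from a response of the keratinocytes here. This reading, with a limit of 2 times the lowest signal tested, was chosen after the values had been seen. The limit was applied to the median signal in control, and the median signal at 96h lay above it. The pan-leukocyte genes had a low median signal (120.5 in control, 138 at 96h), near the level of 67.3 below which genes were left out, the bound equals the change of Laptm5, whose direction depends on the probe sets used, and the values of some of these genes had been seen in the macrophage list. Ptprc rose 1.72-fold, the macrophage list was called (adjusted p = 0.045, and adjusted p = 0.46 with an estimated correlation), and T and NK cell genes passed with no filter (mean 0.30, adjusted p = 2.2e-06; over the alternatives 2.2e-06 to 0.27). These genes also passed camera with the mean of a gene's probe sets (mean 0.17, adjusted p = 0.013). The biological explanation that the design gives, an immune response of the host to the injected cells, was not tested apart from the injection itself.

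Other lists called between both times at the preset correlation were chemokines (-0.68), NF-kappaB feedback (-0.67), endoplasmic reticulum stress (-0.64), wound healing (-0.49), the basal layer (-0.20) and lipid synthesis (0.18). With an estimated correlation 0 of 30 lists were called by camera in this comparison (5 at an unadjusted p under 0.05, and 10 by fry), and the wound healing and basal layer calls ended in 7 and 11 of 23 alternatives. Of the 77 and 11 genes called in opposite directions against control at both times, the 21 that the naming rule covers are given here. They differed by -4.47 (Cxcl1), -4.39 (Egr2), -4.26 (Adm), -4.09 (Ptgs2), -4.01 (Atf3), -3.77 (Egr4), -3.77 (Fosb), -3.63 (Fosl1), -3.61 (Adamts1), -3.47 (Klf2), -3.41 (Edn2), -3.37 (Tnfaip3), -3.30 (Ccn2), -3.19 (Nfkbiz), -2.63 (Pmaip1), -2.58 (Btg2), -1.91 (Hspa1a), -1.80 (Cox7c) and -0.57 (Cdh3). In the other direction Ttll7 differed by 1.28 and Sh3kbp1 by 1.20. Of these, Cdh3 and Tnfaip3 lost a call against control after a change of scaling.

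The 10092 probe sets that name no gene or several, counted without the Affymetrix control probe sets, were not used in the report. Of the 2230 with enough signal to test, 440 changed at 48h against control (358 higher), 262 at 96h against control (47 higher) and 755 between both times (123 higher).

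Other groupings of the arrays were set against the real one. For each comparison of 3 arrays with 3 there are only 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 1519 at 48h, 1378 at 96h and 2577 between both times, where the highest other split gave 0 by limma (1479, 749 and 2033 at an unadjusted p under 0.05). For the F test over 3 groups, 100 of the 280 possible splits were counted. Of these, 1 gave as many genes, the real one with 3140, and the highest other gave 211. A random division of the arrays is an unlikely source of that count. Splits cannot tell the groups from a difference in processing that coincides with them, and the labels name no batch. The bacterial poly-A RNAs had log2 levels of 8.53 to 8.70 on the 96h arrays and 9.34 to 9.47 on all others.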

How the results depend on the processing

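The covariate for the bacterial control RNAs and the gene-by-gene array weights were chosen after the data had been seen, the latter after the planned weights had stopped before convergence and their counts had been read.

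Counts stayed within 1.5 times with quantile normalization, centring on the median, pseudocounts of 1 and 64, no filter, the mean of a gene's probe sets, probe sets open to cross-matching left out, and either other variance model. The share of higher genes between 48h and 96h turned, however, from 34.4% to 63.4% and 58.4% with quantile normalization and centring. Between 48h and 96h the count was 1700 with the lowest 60% left out, where fewer genes were tested (7278), 1664 with only the 2 groups compared, where fewer arrays set the spread, and 1375 with a replicate block (1329 of them shared with the 2577). The replicate numbers showed no sign of pairing: deviations of arrays with the same number had correlations of 0.200, 0.0781 and -0.231, against -0.444 to 0.421 for others. Planned array weights gave 2518 genes at 48h, 5652 at 96h, 6558 by the F test and 1304 shared between both times; gene-by-gene weights gave 4172 at 96h, 5166 by the F test and 984 shared; the cause was not tested. With the covariate 904 genes changed at 96h (767 of the 1378), 836 between both times and 1972 by the F test, and 5 lists changed between both times; the cause was not tested. With every probe set on its own 2706 changed at 48h and 4560 between both times, out of 20975 tested. A threshold of at least 2-fold left 176, 119 and 219 genes by construction.

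Of 30 lists, 14, 11 and 8 passed camera at its preset correlation at 48h, at 96h and between both times. With an estimated correlation 1, 0 and 0 passed, which allows for members that move together by construction, and fry called 17, 6 and 10.

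Without each array in turn the counts ranged from 578 to 2033 at 48h, 397 to 1605 at 96h, 1465 to 2681 between both times and 1686 to 3399 by the F test, with 111 to 470 shared between both times and 12 to 15, 10 to 12 and 6 to 8 lists. Counts moved by over 1.5 times without control replicate 4 (578, 397, F test 1686, shared 111), control replicate 5 (578, 440, 1933, 116), 48h replicate 1 (977 at 48h), 48h replicate 3 (850 at 48h), 96h replicate 2 (631 at 96h, 1546 between both times, 1883, shared 205) and 96h replicate 3 (703, 1465, 2093). Fewer arrays account for a loss of power by construction, but not for which array matters. Control replicate 6 lay nearer to every 48h and 96h array than control replicates 4 and 5. Its SD of log2 differences to 48h replicate 2 was 0.244, against 0.313 and 0.323 for replicates 4 and 5. The SD was 0.145 between replicates 4 and 5, and 0.178 and 0.199 from them to replicate 6. Without control replicate 6 the counts were 1639 at 48h and 1261 at 96h. The lower counts without control replicate 4 or 5 therefore do not mark either as the odd array.

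Of 299 results for named genes, 1 reversed: Laptm5 at 96h was at -0.11 without probe sets open to cross-matching. The 299 include genes named from lists in which no member passed. Those genes had no call to lose, so the share of calls that ended is larger than the counts over 299. Calls ended for 80 with the covariate, 80 without control replicate 4, 72 without control replicate 5, 65 without 96h replicate 2, 65 without 96h replicate 3, 38 without 96h replicate 1, 29 without 48h replicate 1, 29 without 48h replicate 3, 19 without control replicate 6 and 17 without 48h replicate 2. They also ended for 29 with only the 2 groups compared, 24 with centring, 24 of 283 with the mean of a gene's probe sets, 23 with quantile normalization, 18 of 102 with the replicate block, 14 with no filter, 10 with gene-by-gene and 7 with planned array weights, 5 without a variance trend, 4 with a pseudocount of 64, 2 of 277 without probe sets open to cross-matching, 1 with the robust variance model, and 0 with a pseudocount of 1 or a filter at 60%. Of the lists 1 reversed, chemokines at 96h (mean -0.050), which camera placed upwards without a call (0.96) and fry called downwards (0.019). Camera compares a list with the other genes, and the median change over all tested genes at 96h was -0.053. Fry tests a list against no change, so both directions can hold at once. Signal over background limits the genes near the filter at a mean signal of 67.3.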

Other observations

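The hair-type keratin list and the clock gene lists were chosen after some of their genes had been seen to change, and the values expected of the clock genes were set before the remaining ones were looked at.

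Genes of the circadian clock differed between the groups. At 96h Per2 (-1.55), Cry1 (-1.49), Hlf (-1.28), Per1 (-1.17), Per3 (-0.72) and Tef (-0.65) were lower than in control, and Nr1d1 was higher at 48h (2.41) and at 96h (0.80). At 48h Cry1 (-0.89), Hlf (-0.85) and Clock (-0.36) were lower than in control and Ciart (0.67) was higher. Nfil3, which represses clock output genes and also responds to cytokines, rose at 48h (2.15) and fell at 96h (-1.08). Cry1 and Nfil3 belong to the 5 genes listed for the opposite phase. Of 9 tested genes that peak with Dbp, 8 were lower at 96h than at 48h, with a median of -0.72 (95% bootstrap interval over the genes -1.61 to -0.43).

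A difference in the time of day of collection may explain the clock genes in part, but this stays open. Among genes whose values had not been seen, the median of the 5 Dbp-phase genes minus that of the 3 genes of the opposite phase was -0.83 at 96h against control, and the medians (-0.37 and 0.46) had opposite signs, which met the measure set beforehand for such a difference. Over the whole lists the medians also had opposite signs, but with overlapping intervals. The median was -0.65 (95% bootstrap interval -1.28 to -0.19) for 9 Dbp-phase genes. It was 0.20 (-1.49 to 0.52) for 5 genes of the opposite phase, of which Cry1 and Nfil3 fell. The intervals come from resampling the genes of a list, not the arrays. With 5 genes the interval reached from the lowest member, Cry1, to the highest, Arntl. That the overlap of these intervals leaves the matter open was judged after the values had been seen. An immediate early response without a phase change cannot be told apart from it. The median of those Dbp-phase genes, -0.37, lay between the values set beforehand for either outcome. At 96h Nr1d1 rose and Cry1 and Nfil3 fell, each against the median of its list. The lists give no hour of peak for each gene, so these genes cannot decide on a shift of phase. The other 3 opposite-phase genes did not pass at 96h against control (Arntl 0.52, adjusted p = 0.074; Npas2 0.46, 0.11; Clock 0.20, 0.19), and the labels give no hour of collection.

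Hair-type keratin genes were expressed in these preparations, as in the filiform papillae of the tongue, with mean control signals of 3450.2 for Krt36, 3196 for Krt84 and 2445 for Krt32. Of 20 tested genes 5 were lower at 48h (Krtap13, Krt34, Krtap13-1, Krt81 at -0.62 and Krtap4-6 at -0.36), 1 was higher at 96h, and 6 were higher and 2 lower at 96h than at 48h. The list as a whole did not pass camera at any time (adjusted p = 0.25, 0.99 and 0.32).

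The Y-linked gene Eif2s3y had signals of 671 to 824 on the 9 arrays and Xist 41.1 to 61.2.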
